A study of Mus musculus with 31 samples.

How the data were processed

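Primordial germ cells were sorted from mouse embryos (a C57BL/6 cross carrying a germ-cell EGFP reporter, per the labels) and H3K27me3 and H3K9me3 were mapped by ultra-low-input native ChIP-seq. Per the labels' protocols, each ChIP used 1000 cells, chromatin was cut with micrococcal nuclease without fixation, 250 ng of antibody was used, and libraries were sequenced as 100-bp paired ends. The labels list 31 samples, of which 18 are ChIP libraries with a peak list and 13 are input libraries, which are not used here. Groups came from the sample titles: E10.5, E13.5 female and E13.5 male, with 3 libraries of each mark per group. The E10.5 cells were pooled from different embryos, and the labels give them no sex.

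Each of the 18 lists holds broad peaks of 1 ChIP library, called against an input library per the peak names in the files, so peaks were called per sample and not on pooled samples. The peak names of H3K27me3 E10.5 replicate 3 give an H3K9me3 input as its control, and the label of the H3K9me3 input of E10.5 replicate 2 gives E13.5 as its stage against E10.5 in its title. The submitters' processing notes name CASAVA 1.8.4, BWA 0.7.5a, Picard, SAMtools, deepTools 3.3.0 and MACS2 2.1.0, with no role or order, and the build mm9. Peak thresholds and read filters are not given in the sources used here. The deposited scores in columns 5, 7, 8 and 9 are the authors' own values for each peak. By the usual layout of such files column 9 would be a q-value derived from the p-value in column 8, yet column 9 was the larger in 100% of peaks, so the scale of these scores is not known. Scores were used to rank or filter peaks, except in the test of X copy number, which took log2 ratios of column 9. The planned minimums of 2, 3 and 5 on that column and of 3 on column 7 remove no peak, because the lowest values are 11.7 and 10.7. A score minimum of 20 common to all lists, the peaks of each list at or above its own median score, and peaks with a score under 100 were tried in their place, and these were chosen after seeing the data.

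Sequencing depth is unknown, since the lists hold no read counts. The number of peaks per list stands in the report as the closest measure of how much was called, and it sets the precision of each value: lists of 359 peaks (H3K27me3 E13.5 male replicate 2) and 1107 peaks (H3K9me3 E10.5 replicate 3) carry the least. The 359-peak list stands apart in more than length. In it 45.6% of the length lay in H3K9me3 peaks of the same group and number, against 0.0426 to 5.52% in the other pairs. Chromosome 9 held 17.9% of its length, against 3.81 and 3.96% in the other male lists. Overlapping peaks were merged, and 19 peaks on the mitochondrial genome were left out of 265274. The genome length was taken as the sum of the last peak ends per chromosome, 2641.51 Mb, of which chromosome X is 6.31%. Peak ends on chromosomes 1, 7 and 8 pass the ends of the GRCm38 chromosomes, so the annotation at hand, which is of GRCm38, was not used for positions. Results that need promoters (promoters in peaks by gene list, genes that separate groups and the naming of genes) were therefore planned but not run. Only the chromosome and type of each gene were taken from the RefSeq table of GRCm38.p6, for the count of protein-coding genes per autosome.

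For each library the covered length in Mb, the median peak width, and the shares of covered length on X and Y were computed. Group means were compared by exact two-sided permutation tests over all splits, with Benjamini-Hochberg adjustment over the 8 tests of each kind. Exact tests of 3 against 3 libraries cannot go below p = 0.1, and those of 3 E10.5 against 6 E13.5 libraries cannot go below p = 0.0119. Regions that separate groups are 10-kb bins with at least 1 kb in peaks in all libraries of one group and in none of the other. Adjacent bins were merged, and by a rule fixed before the data were examined the 5 longest merged regions per comparison and direction are named, with ties broken by the higher mean column 7 value. That rule also names the 5 called 1-Mb bins with the largest change per direction and the 5 longest runs of bins held by all 9 libraries of a mark, and it always gives X and Y.

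For 1-Mb bins, the share of a library's own peak length in each bin, in ppm, was tested with limma 3.58.1 on log2(ppm + 100), in 1 fit of the 9 libraries of a mark. Bins with peaks in fewer than 3 of the 9 libraries were left out, and calls were made at a Benjamini-Hochberg adjusted p of 0.05. A change on this scale understates the change of bins with little peak length. Shared length of the marks was computed for libraries of the same group and number as log2 of observed over expected, where expected is the product of both covered lengths over the genome length. Replicate overlap is the mean Jaccard index of covered length within groups minus that between groups, with a one-sided exact permutation test over 280 assignments of the 9 libraries. Peak widths were described with no test between lists.

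Alternatives covered the score filters, the bin sizes, the length that counts as shared, the pseudocount, limma array weights (gene-by-gene method), the replicate number as a term, equal numbers of top peaks, and each library left out in turn. The interval code was tested on simulated data against base-by-base counting in 150 cases, with 200 planted separating bins, and 20 permutation p-values were checked against SciPy, with 0 errors. For the limma step, 200 of 1743 bins were changed in simulated data of male against female libraries. At a spread between libraries of 0.5 (SD, log2), 92% of changes of 2 log2 units and 93.5% of changes of 4 were recovered. At a spread of 1 the recovered shares were 3.5% and 68%. All simulated libraries had the same spread, whereas limma array weights of the real H3K27me3 libraries ran from 0.167 to 6.37. The recovered shares therefore do not measure the power of the test on these data. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9, and R 4.3.3, were used.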

Results

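Primordial germ cells, the embryonic precursors of eggs and sperm, were profiled in mouse embryos at E10.5 and E13.5 (embryonic days). H3K27me3, which Polycomb complexes lay down, and H3K9me3, a mark of heterochromatin and repeats, were each mapped in 3 libraries of E10.5 cells, 3 of E13.5 female cells and 3 of E13.5 male cells. The series asked how chromatin changes while DNA methylation is lost across the germ-cell genome. The 18 peak lists held 265274 peaks, 62662 of H3K27me3 and 202612 of H3K9me3, and sequencing depth is unknown. H3K27me3 lists ran from 359 peaks (E13.5 male replicate 2) to 23141 (E10.5 replicate 3), and H3K9me3 lists from 1107 (E10.5 replicate 3) to 56632 (E13.5 male replicate 1). Scores are the authors' own values per peak, of unknown scale, and rank or filter the peaks of each list here, except in the test of X copy number, which used their log2 ratios. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Sample numbers given by the authors leave open whether replicates 1 and 2 of a group are the same samples processed again, in which case n = 3 would overstate the samples. Positions are in mm9 and carry no gene names.

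Peaks of H3K27me3 covered more of the genome at E10.5 than at E13.5, with means of 19.2 ± 16.7 Mb at E10.5, 3.64 ± 1.88 Mb in E13.5 female cells and 2.21 ± 1.93 Mb in E13.5 male cells (SD, n = 3 each). E10.5 replicates 1 and 3 held 19.9 and 35.5 Mb, whereas E10.5 replicate 2 held 2.08 Mb and lay inside the E13.5 range of 0.159 to 5.22 Mb. H3K9me3 peaks covered 50.5 ± 26.8 Mb in E13.5 male cells and 7.51 ± 4.16 Mb in E13.5 female cells (SD, n = 3 each), a ratio of 6.73, and every male library exceeded every female library. At E10.5 the H3K9me3 libraries spread from 0.441 to 46.6 Mb, with a mean of 16.3 ± 26.2 Mb (SD, n = 3).

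An exact permutation test of H3K27me3 length in the 6 E13.5 against the 3 E10.5 libraries gave p = 0.0595 (0.4 adjusted over 8 tests). For H3K9me3 in male against female cells the exact permutation p was 0.1, the smallest that 3 against 3 allows, and 0.4 after adjustment. Exact permutation p-values of the other 6 tests lay between 0.2 and 1, and 5 of these 6 compare 3 with 3 libraries. The H3K27me3 difference of -16.2 Mb became -14.3 Mb (exact permutation p = 0.0119) with a score of at least 20 in every list, a minimum chosen after seeing the data, and -24.8 Mb without E10.5 replicate 2 (p = 0.0357). Without E10.5 replicate 3 it shrank to -8.05 Mb, and without E10.5 replicate 1 it was -15.9 Mb (exact permutation p = 0.179 for both). Without E10.5 replicate 2, the H3K9me3 difference of female from E10.5 cells went from -8.83 to 6.29 Mb. With the score minimum, that of male from E10.5 cells went from 34.2 to -3.74 Mb (19.98 to 49.3 Mb with 1 library left out and all peaks) and that of male from female cells from 43.0 to 4.53 Mb (exact permutation p = 0.1).

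**Figure D1:**
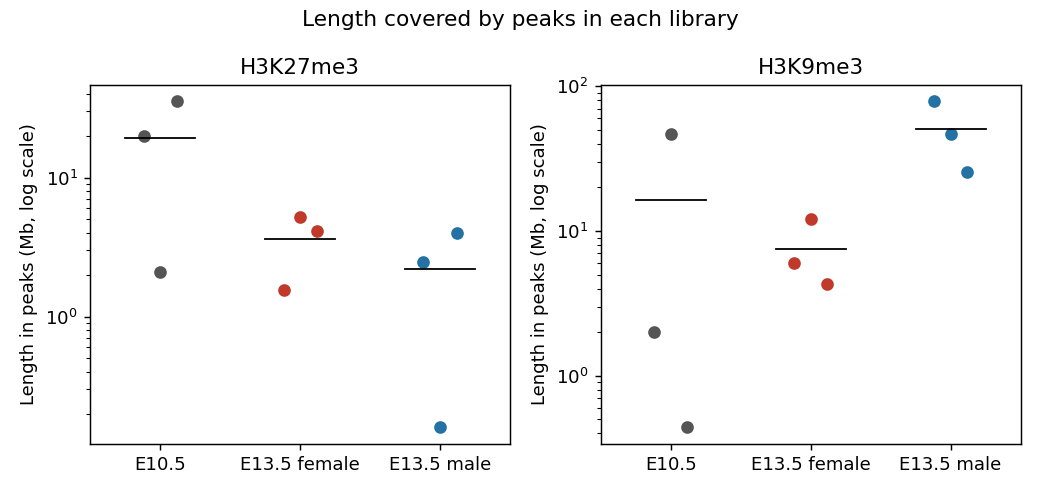
Length in peaks (Mb, log scale) of each library by group, H3K27me3 left and H3K9me3 right; points are libraries and lines are group means. The 3 male H3K9me3 libraries, from 25.7 to 78.9 Mb, lie above the 3 female ones, from 4.28 to 12.2 Mb.

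H3K27me3 peaks were also wider at E10.5. Median widths were 923.5, 827 and 728 bp in the 3 E10.5 libraries, against 431 to 510 bp in female and 283 to 553 bp in male cells at E13.5. Peaks of 5 kb or wider held 26.6 ± 13.9% of the H3K27me3 length at E10.5, 0.411 ± 0.094% in E13.5 female cells and 1.04 ± 1.00% in E13.5 male cells (SD, n = 3 each). The widest E10.5 peak spanned 43733 bp and the widest E13.5 peak 7253 bp. H3K9me3 medians averaged 608 ± 399 bp at E10.5, 452 ± 43.0 bp in female cells and 726 ± 127 bp in male cells (SD, n = 3 each). Widths were described without a test, and the median widths of the E10.5 and E13.5 H3K27me3 lists did not overlap.

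**Figure D2:**
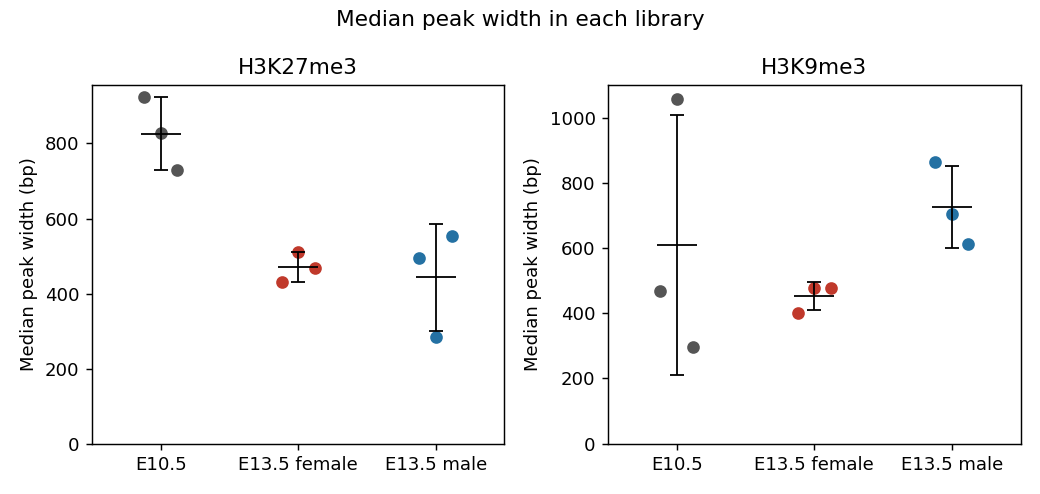
Median peak width (bp) of each library by group, H3K27me3 left and H3K9me3 right; points are libraries, and bars are group means with SD. The lowest E10.5 H3K27me3 median, 728 bp, lies above the highest E13.5 one, 553 bp.

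Chromosome X took a large share of the H3K9me3 peaks in female cells. X held 21.0 ± 1.82% of H3K9me3 length in E13.5 female, 7.10 ± 1.01% in E13.5 male and 10.9 ± 4.51% in E10.5 libraries (SD, n = 3 each), and X is 6.31% of the genome. Female libraries, at 19.9 to 23.1%, lay above every E10.5 library (7.97 to 16.1%) and every male library (6.01 to 8.02%). H3K27me3 was sparse on X in all groups, with 3.23 ± 0.095% of its length there in female, 1.18 ± 1.34% in male and 1.53 ± 0.82% in E10.5 cells (SD, n = 3 each). The 359-peak list of E13.5 male replicate 2 had 2.72%, against 0.484 and 0.325% in the other male libraries. Female germ cells undo X inactivation around these stages. The E10.5 cells have no sex in the labels, and their H3K9me3 lists held 17 to 85 Y peaks. Female against E10.5 cells therefore mixes sex with stage, and it cannot show what the marks do on X during that process.

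Exact permutation p-values for the X share were 0.1 for female against male and for female against E10.5, for either mark, which is the smallest that 3 against 3 allows (0.2 adjusted over 8 tests). Male against E10.5 gave p = 0.8 for H3K27me3 and p = 0.2 for H3K9me3, and E13.5 against E10.5 gave p = 0.464 and p = 0.5 (exact permutation tests). With the 1107 top-ranked H3K9me3 peaks of each list, X held 21.8 to 25.3% in female and 21.3 to 24.2% in male libraries, so that the difference of male from E10.5 cells went from -3.82 to 7.12 points and that of all E13.5 from E10.5 libraries was 7.59 points (exact permutation p = 0.0119). Without E10.5 replicate 3 the male difference with all peaks was -1.23 points. For H3K27me3 the difference of male from E10.5 cells went from -0.356 to 1.02 points with the 359 top-ranked peaks of each list, and to 0.0700 points without E13.5 male replicate 3.

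**Figure D3:**
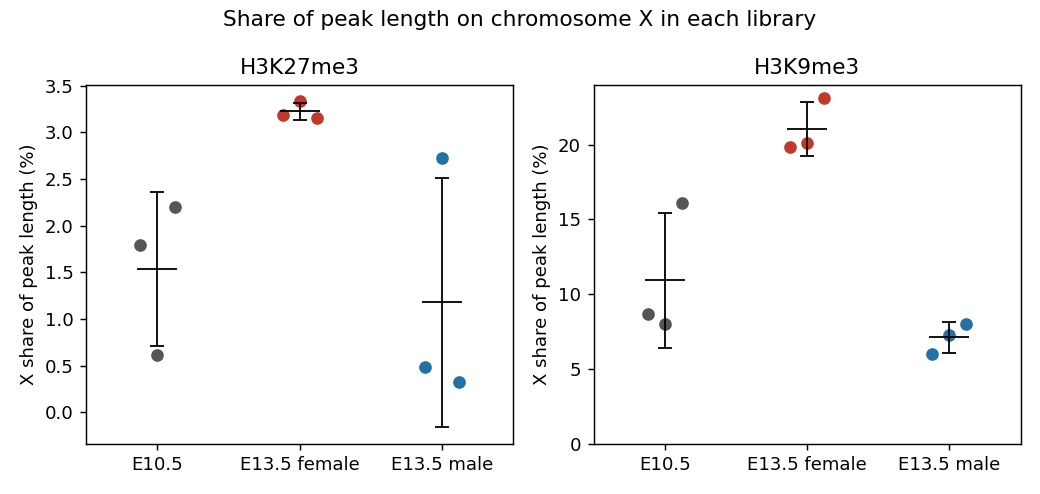
Share of each library's peak length on chromosome X (%) by group, H3K27me3 left and H3K9me3 right; points are libraries, and bars are group means with SD. Female H3K9me3 libraries lie between 19.9 and 23.1%, above the other 6.

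**Figure D4:**
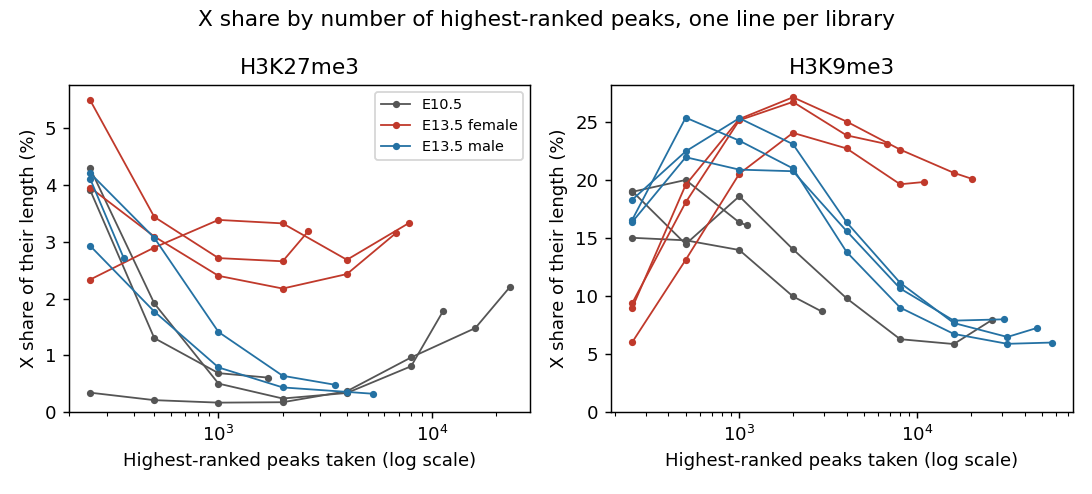
Share of peak length on X (%) against the number of top-ranked peaks taken from each list (log scale), 1 line per library. The female and male H3K9me3 lines meet near 1000 peaks and are apart at 8000, where X holds 19.7 and 22.7% in the 2 female lists of that length and 9.03 to 11.2% in the male lists.

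On chromosome Y, H3K9me3 peaks made up 0.332 ± 0.111% of peak length in male, 0.0326 ± 0.016% in female and 1.90 ± 1.96% in E10.5 libraries (SD, n = 3 each), with at least 87 Y peaks per male list and 5 or 6 per female list. Among E10.5 lists of 0.441, 2.00 and 46.6 Mb the H3K9me3 Y share was 4.12, 1.18 and 0.387%, highest in the shortest list. The male list of 46.9 Mb had 0.352%, so the difference between the E10.5 and male means cannot be told apart from list length. H3K27me3 had at most 2 peaks on Y in any library and 0 in the female lists. Among autosomes, chromosome 19 carried H3K27me3 at 2.1 ± 0.44 times its share of the genome at E10.5, 1.84 ± 0.086 times in female and 1.73 ± 0.078 times in male cells, and chromosome 16 was low at 0.557 ± 0.039, 0.445 ± 0.013 and 0.444 ± 0.024 times (SD, n = 3 each). Chromosome 7 carried H3K9me3 at 1.62 ± 0.62 times its share at E10.5, 1.68 ± 0.21 times in female and 1.94 ± 0.11 times in male cells (SD, n = 3 each). These autosomal and Y values were not tested.

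Most H3K27me3 regions that separated the stages were held by E10.5 and not by E13.5 cells, where a library holds a 10-kb bin with at least 1 kb in peaks. There were 130 bins held by all 3 E10.5 libraries and by none of the 6 E13.5 libraries, and 3 bins with the opposite arrangement. E10.5 replicates 1 and 3 covered 19.9 and 35.5 Mb, replicate 2 covered 2.08 Mb, and E13.5 lists covered 0.159 to 5.22 Mb. The direction, here and against each sex alone, thus cannot be told apart from the length of the lists. The longest E10.5 region, chromosome 4 from 88930001 to 88960000, held 15.0 ± 7.47 kb in peaks at E10.5 (SD, n = 3) and at most 0.959 kb in any E13.5 library. Chromosome 11 from 84330001 to 84350000 held 10.2 ± 2.68 kb at E10.5 (SD, n = 3) and 0 kb at E13.5. E13.5 cells of both sexes had H3K27me3 at chromosome 10 from 57680001 to 57700000, with 7.31 ± 2.32 kb (SD, n = 6) against 0 kb at E10.5.

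The other named E10.5 regions were chromosome 6 from 85130001 to 85150000 with 11.7 ± 3.45 kb, chromosome 2 from 146040001 to 146060000 with 7.62 ± 5.16 kb, and chromosome 16 from 91260001 to 91280000 with 7.04 ± 5.64 kb (SD, n = 3 each). At E13.5 the second region was chromosome 8 from 56200001 to 56210000, with 2.94 ± 1.49 kb (SD, n = 6) against at most 0.593 kb at E10.5. Against female cells alone, 191 bins were held by E10.5 and 3 by female libraries, among the former chromosome 10 from 79950001 to 79970000, chromosome 16 from 18580001 to 18600000 and chromosome 7 from 86680001 to 86700000. Against male cells alone the counts were 210 and 3, and E10.5 regions included chromosome 3 from 128910001 to 128940000 and chromosome 1 from 78200001 to 78220000. These chromosome 10 (from 57680001) and chromosome 8 regions were the E13.5 regions in each sex taken alone.

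For 3 against 6 libraries, 4 of 84 splits gave a count as large as the 133 bins found, and for pairs of groups 3 and 2 of 10 splits did. Leaving out E10.5 replicate 2, whose list is the shortest of its group, gave 2755 H3K27me3 bins between the stages, 3078 against female and 3627 against male cells, and leaving out E13.5 male replicate 3 gave 331 against male cells. Without the short list of E13.5 male replicate 2, the bins held by male and not by E10.5 cells rose from 3 to 20. When any overlap counted, the chromosome 16 region from 91260001 was no longer held by E10.5 alone, since 4 of the 6 E13.5 libraries had some peak length there.

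Between the sexes at E13.5, H3K27me3 separated 50 bins, all held by the female and by none of the male libraries. Without the 359-peak list of E13.5 male replicate 2, male cells alone held 77 further bins. Chromosome 17 from 48040001 to 48060000 held 7.68 ± 1.39 kb in female libraries and at most 1.06 kb in a male library, and chromosome 3 from 128910001 to 128930000 held 3.91 ± 0.62 kb against 0 kb (SD, n = 3). On X, 20-kb regions from 7490001 to 7510000 and from 7540001 to 7560000 held 4.53 ± 1.13 and 6.26 ± 1.85 kb in female libraries and 0 kb in male libraries (SD, n = 3). Chromosome 19 from 46500001 to 46520000 held 4.32 ± 0.99 kb against at most 1.24 kb (SD, n = 3). The chromosome 3 region also had peaks in all E10.5 libraries, and 5 of the 50 bins were on X.

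The count moved with the libraries and the rule, since 3 of 10 splits gave as many bins. Without E13.5 female replicates 1 and 3 in turn it was 239 and 91, without E13.5 male replicate 2 it was 127 (50 female and 77 male bins) and without replicate 3 it was 108, and it was 0 where at least 50% of a bin had to lie in peaks.

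H3K9me3 separated the sexes in the other direction, with 3719 bins held by all male and no female libraries and 0 the other way. Every male list also covered more length than every female list (25.7 to 78.9 against 4.28 to 12.2 Mb). The split by sex is thus also the split by peak length, and the count cannot tell sex from length. Chromosome 7 from 15250001 to 15330000 held 27.3 ± 10.6 kb in male libraries (SD, n = 3) and at most 3.78 kb in a female library. Y from 2840001 to 2910000 held 49.7 ± 4.69 kb in male and 0 kb in female libraries, and X from 122620001 to 122680000 held 24.3 ± 4.77 kb against at most 1.34 kb (SD, n = 3). Chromosome 11 from 73920001 to 73990000 held 28.0 ± 9.33 kb and chromosome 9 from 19670001 to 19740000 held 25.7 ± 11.4 kb in male libraries (SD, n = 3), with at most 3.12 and 2.38 kb in a female library. Of the 3719 bins, 186 were on X.

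E10.5 replicates 1 and 3 covered only 2.00 and 0.441 Mb in H3K9me3 peaks, against 25.7 to 78.9 Mb in the male lists. Counts of male against E10.5 bins therefore cannot tell stage from list length either. Compared with E10.5, male cells held 941 H3K9me3 bins alone and E10.5 cells 0. The longest were chromosome 3 from 20640001 to 20670000 with 6.53 ± 0.72 kb in male libraries, chromosome 3 from 69750001 to 69770000 with 3.61 ± 1.15 kb, chromosome 7 from 10930001 to 10950000 with 4.15 ± 0.88 kb and from 9250001 to 9270000 with 7.83 ± 4.56 kb, and chromosome 9 from 12450001 to 12470000 with 8.45 ± 5.08 kb (SD, n = 3 each). E10.5 cells held 15 bins that female cells lacked, 6 of them on X, and the longest regions were Y from 2850001 to 2900000 with 25.5 ± 18.8 kb and from 2780001 to 2800000 with 7.27 ± 5.93 kb, and X from 120110001 to 120130000 with 9.004 ± 5.24 kb, from 120320001 to 120340000 with 7.45 ± 6.42 kb and from 121300001 to 121310000 with 5.62 ± 1.84 kb (SD, n = 3 each). Female cells held 2 bins that E10.5 cells lacked, X from 52860001 to 52870000 with 1.13 ± 0.16 kb and X from 28680001 to 28690000 with 1.24 ± 0.24 kb (SD, n = 3 each). The E10.5 cells have no sex in the labels and their lists held Y peaks, so the female comparison with E10.5 mixes sex with stage. No H3K9me3 bin separated E10.5 from all 6 E13.5 libraries.

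As many bins came from 1, 2 and 6 of 10 splits for male against female, male against E10.5 and female against E10.5, and with a score of at least 20 in every list male against female cells gave 290 male and 6 female bins. Male against E10.5 cells fell from 941 to 26 bins with that minimum and to 8 where at least 50% of a bin had to lie in peaks. Leaving out E13.5 male replicate 3 gave 9482 bins between the sexes and 4462 against E10.5, and leaving out E13.5 male replicate 2 gave 1566 against E10.5. Leaving out E10.5 replicate 2 gave 6041 against male and 155 against all E13.5 cells (1 to 7 without E10.5 replicate 1 or 3 or any 1 female library). The direction of the female comparison with E10.5 rested on single lists and on the rule. With all lists kept, E10.5 cells held 6 and female cells 11 bins of 50 kb. Among peaks with a score under 100 the numbers were 2 and 6. E10.5 and female cells held 15 and 166 bins (181) without E10.5 replicate 2, 216 and 2 (218) without E10.5 replicate 3, 15 and 18 (33) without E13.5 female replicate 1, 15 and 36 (51) without E13.5 female replicate 3, and 28 and 132 with any overlap.

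In 1-Mb bins, H3K27me3 shifted at a few places relative to each library's total. Male libraries had 62.9 ± 54.9 ppm of their H3K27me3 length on chromosome 18 from 66000001 to 67000000, against 3681 ± 513 ppm at E10.5 and 5345 ± 1128 ppm in female libraries (SD, n = 3 each). That bin fell by 4.59 ± 0.51 on the log2 scale from E10.5 to male cells (SE, limma adjusted p = 0.00466) and changed by -5.11 ± 0.51 from female to male cells (adjusted p = 0.00169). Chromosome 10 from 57000001 to 58000000 rose by 5.20 ± 0.75 from E10.5 to E13.5 (SE, limma adjusted p = 0.0260), and chromosome 11 from 74000001 to 75000000, at 637 ± 50.2 ppm at E10.5 (SD, n = 3), had 0 ppm in all 6 E13.5 libraries and fell by 2.88 ± 0.39 (SE, adjusted p = 0.0260). The size of the chromosome 11 fall is bounded by the 100 ppm added before the log. A 0 in the list of E13.5 male replicate 2, which covers only 0.159 Mb, carries little. The chromosome 10 bin held 15.7 ± 27.2 ppm at E10.5, 3012 ± 1281 ppm in female and 11194 ± 14942 ppm in male libraries (SD, n = 3 each). In male libraries the SD exceeded the mean, so the size of the rise there is uncertain.

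From E10.5 to male cells 12 of 1743 tested bins passed, 2 of them higher and 10 lower in male cells. The higher bins were chromosome 10 from 57000001 (5.69 ± 0.86, SE) and chromosome 8 from 56000001 (4.18 ± 0.81), and the largest falls besides chromosome 18 were on chromosome 17 from 24000001, chromosome 7 from 148000001, chromosome 8 from 80000001 and chromosome 19 from 56000001, with log2 changes of -3.11 to -2.88 (limma adjusted p = 0.0347 to 0.0493). The higher chromosome 8 bin held 3046 ± 3664 ppm in male libraries (SD, n = 3), again with an SD above the mean. Over both sexes 6 bins passed, with changes of -2.45, -2.71 and -2.96 on chromosome 7 from 131000001, 147000001 and 148000001 and of -2.47 on chromosome 2 from 109000001 besides the chromosome 10 and 11 bins. Male against female gave the chromosome 18 bin alone, and female against E10.5 gave 0 bins with limma, with 134 at an unadjusted p under 0.05. For H3K9me3, limma called 0 of 2516 bins in any of the 4 contrasts, with 182 to 377 bins at an unadjusted p under 0.05.

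These counts moved with the setting: limma array weights gave 152, 223, 41 and 329 H3K27me3 bins for female and male against E10.5, male against female and E13.5 against E10.5, and 2-Mb bins gave 0 in all 4. With the replicate number as a term, the H3K27me3 counts in the same order were 0, 1, 1 and 0. From E10.5 to male cells the 12 H3K27me3 bins became 0 without E10.5 replicate 1 or 3, 26 without E10.5 replicate 2, 1 without E13.5 female replicate 2 or 3, and 4 and 2 without E13.5 male replicates 1 and 3. Between the stages the 6 bins became 0 without E10.5 replicate 1 or 3 or any female library, 1 without E10.5 replicate 2 or E13.5 male replicate 3, and 2 without E13.5 male replicate 1. Without E10.5 replicate 2 there were 28 bins between the sexes and, for H3K9me3, 207, 328, 1 and 332 bins in the 4 contrasts. H3K27me3 gave 2 bins between the sexes without E13.5 male replicate 1 and 6 from E10.5 to female cells without E13.5 male replicate 2, and H3K9me3 gave 6 between the sexes without E10.5 replicate 3.

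A few regions carried at least 1 kb of a mark in every library of it, and lesser lengths are not counted here. At the start of chromosome 9, from 3000001 to 3030000, all 9 H3K27me3 and all 9 H3K9me3 libraries had peaks, and chromosome 2 from 98500001 to 98510000 had them in 9 H3K27me3 and 8 H3K9me3 libraries. Top H3K27me3 scores per list were 276 to 586 and 335 to 575 in these 2 regions, against 19.8 to 66.5 in the 3 regions named next. Whether peaks there reflect both marks or an artefact was not tested. Chromosome 1 from 173000001 to 173010000, chromosome 4 from 88420001 to 88430000 and chromosome 5 from 120880001 to 120890000 had H3K27me3 in 9 libraries and H3K9me3 in 0. For H3K9me3 in all 9 libraries and H3K27me3 in 0, the named regions were chromosome 7 from 67000001 to 67040000, chromosome 1 from 85320001 to 85340000, chromosome 10 from 7230001 to 7240000 and chromosome 17 from 13740001 to 13750000. In all, 8 bins of 10 kb held H3K27me3 and 24 held H3K9me3 in every library of the mark.

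The marks shared between 15.1 and 149 kb of peak length per group and replicate number. On the log2 scale this was 2.06 ± 1.09 above expectation at E10.5, 2.21 ± 2.31 in E13.5 female and 2.13 ± 2.22 in E13.5 male cells (SD, n = 3 each). With only peaks scoring under 100 the libraries ranged from -1.19 to 2.23 at E10.5, from -1.47 to 3.86 in female and from -0.21 to 3.28 in male cells. The exact permutation p was 1 in each of 3 comparisons, and the direction of the differences turned when single libraries were left out. With a score of at least 20 in every list, female and male cells lay above E10.5 by 3.20 and 3.15 (exact permutation p = 0.1 each, the smallest that 3 against 3 allows).

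H3K27me3 libraries had a mean Jaccard index of 0.117 within and 0.0779 between groups (one-sided exact permutation p = 0.1). The H3K9me3 indices were 0.110 and 0.0752 (one-sided exact permutation p = 0.104), and 0.00357 was the smallest p that 280 assignments allow. With a score of at least 20 in every list the permutation p became 0.0179 for H3K27me3 and 0.00357 for H3K9me3, whereas with the shared length divided by the shorter list the H3K9me3 overlap within minus between groups was -0.0373. E10.5 replicates 1 and 3 alone had an H3K27me3 index of 0.401, and without replicate 1 or 3 the excess within groups fell from 0.0392 to 0.00365 or 0.00274. For H3K9me3 it fell from 0.0350 to 0.00275 or 0.00268 without E13.5 male replicate 1 or 2 and rose to 0.0879 without E10.5 replicate 2 (one-sided exact permutation p = 0.00357). That H3K9me3 library had indices of 0.304, 0.255 and 0.233 with the 3 male libraries, whose own indices were 0.185 to 0.275, but of 0.0382 and 0.0075 with the other E10.5 libraries, whose lists are far shorter.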

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

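The tests of peak list length were chosen after the result was seen. Those of X copy number and of peak width were also chosen after the data were seen, though written down before their own values were computed. Peaks on the mitochondrial genome, which lie outside the measurement, numbered 7 in the H3K27me3 list of E13.5 male replicate 3, 7 in the H3K9me3 list of E13.5 female replicate 2 and 4 in that of E13.5 male replicate 3. H3K9me3 covered length stood out because every female library lay below and every male library above the E10.5 mean, with male minus female at 43.0 Mb. The X share of H3K9me3 stood out in the same way with the sexes exchanged, at -13.9 points for male minus female. The E10.5 mean length rests on replicate 2 (46.6 Mb), since replicates 1 and 3, at 2.00 and 0.441 Mb, lay below every female library (4.28 to 12.2 Mb). The E10.5 X shares were 8.69, 7.97 and 16.1% in replicates 1 to 3, the first 2 close to the male range of 6.01 to 8.02%. Neither difference between the sexes' changes from E10.5 was tested, beyond the exact permutation test of male against female, whose p of 0.1 is the smallest possible.

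The X chromosome held a larger share of H3K9me3 peak length in E13.5 female than in male cells, 21.0 against 7.10%. The presence of 2 X copies in female cells stays open. In regions with peaks in both sexes and a male score of at least 20, the female to male score ratio was compared between X and autosomes. The excess on X was 0.059 on the log2 scale (95% bootstrap interval over regions, 0.013 to 0.091). The bootstrap drew regions and not libraries, so the interval holds no spread between libraries. These regions hold only 20.7 to 34.4% of the female X peak length, and the scale of the scores is unknown. List length stays open too, because the female minus male difference was 10.7 points with the top 6719 peaks of each list and 0.945 points with the top 1107, where the sexes overlapped, and so neither can be told apart from a difference between female and male chromatin. Among the top 250 peaks the order was the other way, with X at 6.02 to 9.38% in female and 16.4 to 18.3% in male lists. A lasting or returning H3K9me3 domain on the female X is a biological possibility that the design names only as sex, and it was not tested further. The E10.5 cells were pooled and have no sex in the labels, so these libraries cannot tell lasting from returning.

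H3K27me3 peaks were wider in E10.5 than in E13.5 cells. The tables argue against a larger number of called peaks as the whole cause, since with the top 359 peaks of each list the narrowest E10.5 median (361 bp) still exceeded the widest E13.5 median (297 bp), by 64 bp, although E10.5 medians there spread over 361, 438 and 2020 bp. They argue against different score minimums too, since with a score of at least 20 the gap was 282.5 bp (827.5 against 545 bp). Sequencing depth and the quality of each ChIP are not recorded in the lists and stay open as technical explanations. A change in the breadth of H3K27me3 domains with stage is therefore 1 candidate explanation among those open.

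Chromosome X held less of the H3K27me3 peak length in E13.5 male than in female cells, 1.18 against 3.23%. X copy number stays open here as well. The excess of the score ratio on X was -0.0010 on the log2 scale (95% bootstrap interval over regions, -0.16 to 0.18). Regions were chosen in the same way and hold only 1.48 to 12.5% of the female X peak length. List length is open too: the difference was 2.45 points with the top 2629 peaks of the 5 lists that reach it, close to the 2.82 points with all their peaks, yet with the top 359 peaks it was 0.736 points and female (3.52 to 4.45%) and male (2.42 to 3.98%) lists overlapped. Neither can thus be told apart from a difference by sex, which was not tested further. E13.5 male replicate 2, with 359 peaks and an X share of 2.72%, does not reach the larger number.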

How the results depend on the processing

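The score minimum of 20, the peaks at or above each list's median score, the peaks with a score under 100, equal numbers from the lists compared, and all peak-width alternatives were tests chosen after the data were seen; the other alternatives were planned. Planned score minimums of 2, 3 and 5 and a column 7 minimum of 3 remove no peak, so they say nothing. Promoter results and their alternatives were not run, because the annotation at hand is of another build, and the rule of 2 in 3 libraries was run for pairs of groups. Of the alternatives, 88 of 94 for covered length, 108 of 118 for X share, 25 of 36 for the overlap of marks, 22 of 30 for replicate overlap, 9 of 11 for peak width, 53 of 116 for separating regions and 94 of 152 for 1-Mb bins kept direction and side of the threshold or, for counts, stayed within 1.5 times, but pairs of 3 libraries cannot pass the threshold at all. A kept result can therefore have shrunk greatly. For H3K9me3 in male against female cells, the X share went from -13.9 to -0.945 points with equal numbers of top peaks of the mark. Covered length in the same comparison went from 43.0 to 4.53 Mb with the score minimum of 20, and both count as kept. Among single named items, 126 of 229 checks of 1-Mb bins lost the call and none turned, and 97 of 215 checks of regions moved; in 1 more (coded -1, any overlap) the chromosome 16 region from 91260001 lost its call, because 4 of 6 E13.5 against 3 of 3 E10.5 libraries had some peak length there. Unknown depth and short lists limit all of these, and the cause of the changes below was not tested except where fewer peaks or libraries are part of the setting.

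With the score minimum of 20, covered length differed by -14.3 Mb for H3K27me3 in E13.5 against E10.5 (exact permutation p = 0.0119), -3.74 Mb for H3K9me3 in male and -6.01 Mb in all E13.5 against E10.5 cells, and 4.53 Mb for H3K9me3 in male against female cells (43.0 Mb with all peaks). On the log2 scale H3K9me3 in female against E10.5 cells turned to 0.98. Leaving out 1 library gave -24.8 to -8.05 Mb for H3K27me3 in E13.5 against E10.5 (lowest without E10.5 replicate 2), -16.8 to 6.29 Mb for H3K9me3 in female against E10.5 and 19.98 to 49.3 Mb in male against E10.5 (both highest without E10.5 replicate 2). The H3K27me3 X share of male minus E10.5 cells turned to 1.02 points with equal numbers of top peaks (of the mark or of the lists compared), 0.472 with the score minimum and 0.821 with peaks at or above the median score, and ran from -1.13 to 0.0700 with 1 library left out. For H3K9me3 it turned to 7.12 points with equal numbers and 2.88 with the score minimum and ran from -5.30 to -1.23 with 1 library left out (highest without E10.5 replicate 3), and E13.5 minus E10.5 was 7.59 with equal numbers (exact permutation p = 0.0119). The H3K27me3 width difference of E13.5 from E10.5 was -659.5 bp with equal numbers of peaks, which rests on E10.5 replicate 3 (medians of 361, 438 and 2020 bp), and -715 bp with the score minimum.

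Counts of separating bins follow in the order female against E10.5, male against E10.5, male against female, and E13.5 against E10.5, starting from 194, 213, 50 and 133 for H3K27me3 and 17, 941, 3719 and 0 for H3K9me3. Bins of 2 kb gave 430, 452, 17 and 309, and 6, 621, 2179 and 0. Bins of 50 kb gave 117 with E10.5 alone and 2 with female alone (1.2e2 together), 137, 49 and 80, and 17, 744, 2538 and 4. Any overlap gave 233, 297, 178 and 127, and 160, 3634, 5191 and 66. At least 50% of a bin gave 47, 40, 0 and 37, and 0, 8, 128 and 0. The score minimum of 20 gave 387, 357, 10 and 273, and 18, 26, 296 and 0. Peaks at or above the median score gave 129, 153, 35 and 84, and 22, 411, 1866 and 5. Scores under 100 gave 194, 213, 50 and 133, and 8, 954, 3693 and 4. In the H3K9me3 comparison of female with E10.5 cells, the 17 bins of 50 kb were 6 with E10.5 and 11 with female alone. The 8 bins with scores under 100 were 2 and 6, so both turned the direction. The rule of 2 in 3 libraries gave 3102, 3656 and 373, and 275, 5227 and 10859 for the pairs of groups. With 1 library left out the H3K27me3 counts ran from 199 to 3078, 213 to 3627, 66 to 239 and 133 to 2755, and the H3K9me3 counts from 19 to 218, 946 to 6041, 3914 to 9482 and 0 to 155, with the highest value without E10.5 replicate 2 in 5 of the 8; the others were without E13.5 female replicate 1, E10.5 replicate 3 and E13.5 male replicate 3.

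Counts of called 1-Mb bins, in the same order, start from 0, 12, 1 and 6 for H3K27me3 and 0 in all 4 for H3K9me3. A pseudocount of 20 ppm gave 0, 1, 0 and 3 for H3K27me3, and 500 ppm gave 2, 13, 3 and 16, and 12, 0, 3 and 0 for H3K9me3. All bins with any peak gave 4, 21, 3 and 19 for H3K27me3. Array weights gave 152, 223, 41 and 329, and 0, 0, 159 and 0. Bins of 500 kb gave 0, 9, 0 and 11, and 17, 1, 0 and 1, and bins of 2 Mb gave 0 in all 4, and 4, 0, 0 and 0. The score minimum of 20 gave 10, 15, 7 and 42, and 1, 0, 4 and 0, and peaks at or above the median score gave 0, 5, 1 and 4, and 15, 0, 0 and 0. With 1 library left out the H3K27me3 counts ran from 0 to 6, 0 to 26, 1 to 28 and 0 to 9, and the H3K9me3 counts from 0 to 207, 0 to 328, 0 to 6 and 0 to 332, with the highest value without E10.5 replicate 2 in 5 of the 8, without E13.5 male replicate 2 in 2 and without E10.5 replicate 3 in 1.

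The log2 overlap of marks in male against E10.5 cells turned to -0.016 with 100 random shifts as expectation, and in male against female cells to 0.23 with scores under 100, and with the score minimum female and male cells exceeded E10.5 by 3.20 and 3.15 (exact permutation p = 0.1 each). With 1 library left out the differences ran from -1.03 to 1.27 for female against E10.5, -1.20 to 0.84 for male against E10.5 and -1.35 to 1.11 for male against female. Replicate overlap within minus between groups was 0.0789, 0.0575 and 0.0643 for H3K27me3 with the overlap coefficient, the share of peaks overlapping by at least 50% and the score minimum (one-sided exact permutation p = 0.0214, 0.00714 and 0.0179), and with 1 library left out it ran from 0.00274 (without E10.5 replicate 3; 0.00365 without E10.5 replicate 1) to 0.0576. For H3K9me3 the first 2 measures turned it to -0.0373 and -0.0061, equal numbers of top peaks gave 0.121 and the score minimum 0.0717 (one-sided exact permutation p = 0.00357 for both), and with 1 library left out it ran from 0.00268 to 0.0879, highest without E10.5 replicate 2 (one-sided exact permutation p = 0.00357).

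Replicate numbers were not shown to pair these samples: deviations of same-numbered libraries correlated at -0.212 to 0.204 for H3K27me3 and -0.0574 to 0.119 for H3K9me3, and not every library correlated best with its own number. The 3 H3K27me3 pairs of replicate 3, which was deposited apart from replicates 1 and 2, correlated at 0.142, 0.144 and 0.204, and the labels name no batch. With the number as a replicate block, the H3K27me3 1-Mb counts were 0, 1, 1 and 0, and H3K9me3 stayed at 0 bins in all 4 contrasts. Within each of the 3 numbers X held more of either mark in the female than in the male library.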

Other observations

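The comparison of peak positions between unions, the windows along X and the counts of splits for separating regions were chosen after the data were seen, whereas the tests of gene density and the splits of the 1-Mb bin test were set before. Most H3K27me3 peak length left at E13.5 lay where E10.5 cells had peaks. On autosomes, 81.6 ± 5.62% of the length in female and 83.1 ± 3.74% in male libraries fell in the union of the E10.5 peaks, which covers 1.56% of the autosomes, and on X 67.3 ± 10.4% and 65.2 ± 13.6% did (SD, n = 3 each). That union is the largest, at 39.6 Mb against 9.04 Mb (female) and 5.71 Mb (male). Relative to each union's share of the autosomes, female length lay in the E10.5 union 52.2 times and in the male union 145 times. Male length lay in the E10.5 union 53.2 times and in the female union 152 times. The smaller a union, the higher the value it can reach, and the female and male unions cover only 0.353 and 0.230% of the autosomes. These values therefore cannot rank the unions by how well their positions match.

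H3K9me3 peaks of female cells lay within the union of male peaks for 83.7 ± 2.37% of their autosomal length but for 51.7 ± 5.34% of their X length (SD, n = 3 each), and that union covers 3.95% of the autosomes and 4.35% of X. E10.5 libraries had 86.5 ± 7.82% and 82.0 ± 14.6% of their length in it (SD, n = 3 each). Along X, the window from 120 to 130 Mb held 23.7 ± 9.005% of the H3K9me3 length on X at E10.5, 15.8 ± 1.54% in male and 4.51 ± 0.72% in female libraries (SD, n = 3 each).

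A hypothesis set before its test was that gene-rich autosomes hold more H3K27me3 peak length. Over the 19 autosomes, H3K27me3 length relative to chromosome length rose with protein-coding genes per Mb (Spearman rho 0.707, permutation p = 0.00103, adjusted over 2 tests 0.00206; Pearson r 0.622, permutation p = 0.00477), and r was 0.764 without chromosomes 7 and 11. Chromosome 19, with 11.5 genes per Mb, stood at 1.89 times its share of the genome and chromosome 16, with 6.91, at 0.482 times. The opposite hypothesis for H3K9me3, that gene-poor autosomes hold more of it, was not borne out (rho -0.142, permutation p = 0.561, adjusted 0.561; r 0.166, p = 0.501, and r -0.217 without chromosomes 7 and 11), and gene-rich chromosome 7 had the highest value, 1.75 times. Gene numbers are those of the GRCm38.p6 RefSeq table and lengths are the last peak ends in mm9, and chromosomes are not independent replicates.

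Splits of the same libraries give a scale for the counts of separating bins, and chance alone gives each of 10 splits on average 10% of the bins held by exactly 3 of 6 libraries. With 10 splits of 3 and 3 libraries no share under 0.05 can be had: for H3K27me3, female against E10.5 gave 194 bins (3 splits as large, highest other 494), male against E10.5 gave 213 (2 splits, highest other 423) and male against female gave 50 (3 splits, highest other 126). For H3K9me3 these were 17 (6 splits, highest other 368), 941 (2 splits, highest other 3137) and 3719 (1 split, highest other 602). The split that gave 3719 also sets the 3 lists with the longest peak length apart from the 3 shortest, so sex and length cannot be told apart there. Over 84 splits, E13.5 against E10.5 gave 133 H3K27me3 bins, with 4 splits as large, a share under 0.05, yet the highest other split gave 356 and set apart the 3 lists with the longest peak length, E10.5 replicates 1 and 3 and E13.5 female replicate 2, a structure of the samples that follows this length. For H3K9me3 the real split gave 0 bins, which all 84 splits match by definition, so the count says nothing about chance, and the highest, 2454, again set the 3 lists with the longest peak length apart.

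In the 1-Mb bin test, 10 splits allow no share under 0.05 either. For H3K27me3, limma gave 0 bins for female against E10.5 (10 splits as large, highest other 0, 134 bins at an unadjusted p under 0.05), 12 for male against E10.5 (1 split, highest other 11) and 1 for male against female (1 split, highest other 0). Over 84 splits the 6 bins of E13.5 against E10.5 were matched or passed by 4 splits, a share under 0.05, but 1 split gave 48 bins, several times the real count, and set apart the 3 lists with the shortest peak length, E10.5 replicate 2, E13.5 female replicate 1 and E13.5 male replicate 2, again a structure that follows this length. For H3K9me3 limma gave 0 bins in each comparison, with 273, 374, 182 and 377 at an unadjusted p under 0.05; the highest other splits gave 80, 0 and 0 of 10 for the pairs of groups (10 splits as large in each) and 269 for the stages (84 of 84 splits as large), and counts of 0 say nothing about chance.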
